A study of Halobacterium salinarum NRC-1 with 16 samples.

How the data were processed

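Transcripts of *Halobacterium salinarum* NRC-1, a salt-loving archaeon, were measured on 16 arrays with 2 colours each. The labels describe the strain as a knockout of *ura3* (*pyrF*) and vng1179. The labels give 4 copper doses (0.0, 0.7, 0.85 and 1.0 mM) and a set A and a set B at each dose, which makes 8 samples. Each sample was hybridised on 2 arrays with the dyes swapped, against a common control RNA of NRC-1. The labels do not say whether the sets came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The growth text of the dye-swapped arrays names an iron salt where their titles name copper; the titles were followed. By their array numbers the doses 0.0 and 0.7 mM fall into one run and 0.85 and 1.0 mM into another. The array with set A of 0.85 mM in channel 1 stands outside both runs and its label names another dye.

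The deposited unit was a log ratio of the 2 channels for each spot, per the labels and the values themselves. What the authors did to scale or centre it, how background was handled and the base of the logarithm are not given in the sources used here. The base could not be settled from the values, although the tests had been planned for log2 values, so every change is given in the deposited log-ratio unit and a fold is given only with the base it assumes. Array medians lay between 0.10 and 0.19, so the deposited values were not centred on 0. The values carry a dye effect larger than the differences between samples. Correlations between arrays were taken as deposited across features, each the mean of its spots without exact zeros. Arrays of the same orientation correlated at a median of 0.93 (56 pairs) and arrays of opposite orientation at 0.66 (64 pairs). Changes at 0.7, 0.85 and 1.0 mM correlated between the orientations at -0.36, 0.06 and -0.21 as deposited. From the negative values the dye swaps were read as not yet turned, which the value at 0.85 mM does not bear out. In the same order, changes of the mean without turning correlated between set A and set B at 0.0092, 0.55 and 0.62. Changes of the turned mean did so at 0.56, 0.55 and 0.76. The ratio was read as channel 1 over channel 2 from the order of the labels, which is likely but not stated; if it runs the other way, every higher and lower below changes places.

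Arrays with the sample in channel 2 had their sign turned so that every ratio was sample over control RNA, and the dye-swap arrays of a sample were averaged, which cancels a dye effect that is equal in both. An exact 0, found at 1175 spots on 8 arrays, was taken as a missing value, and the matching spot of the dye-swap partner was left out with it. The 10752 spots fall into 2688 features of 4 spots each, of which 2675 had a value in all 8 samples and were tested. The platform annotation names 133 of them with a gene symbol; the other 2542 are given by the number of their first probe, and at most 2 of these are named per direction. All 133 symbols were also found in a RefSeq gene table of another strain (91-R6), which was used for no coordinates. Signal and background intensities were not analysed here. Precision rests on the spread between the means of the 8 samples: the median standard error of a difference between doses was 0.034 log-ratio units.

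Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the means of the 8 samples, no covariates), with Benjamini-Hochberg adjustment over the 2675 features and a threshold of 0.05 on the adjusted p. The comparisons were each copper dose against 0.0 mM, the mean of the 3 copper doses against 0.0 mM, a linear trend over mM, 1.0 against 0.85 mM, and 0.0 mM against the control RNA. The last tests a mean ratio against 0 and leaves out the spread of the control itself. The 4 doses share an estimate of the spread with 4 residual degrees of freedom (6 for the trend). Gene lists with at least 3 named members were tested with camera at a preset correlation of 0.01, and with an estimated correlation, which set the list against all other genes, and with fry, which tests the list against no change; each was adjusted over 64 tests (16 lists in 4 comparisons). Of 19 lists planned, 5 could be tested, 6 had under 3 named members and 8 had none, copper efflux among them; 11 lists were added from the gene symbols after the annotation had been read.

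The comparisons, tests, thresholds, planned lists, alternatives and the rule for naming genes were chosen before the data were examined; taking an exact 0 as missing, the 11 further lists and the comparison of 1.0 with 0.7 mM were chosen after. That rule takes the genes labelled as knocked out first, then, per comparison and direction, the 8 named genes and 2 unnamed features with the largest change among those past the threshold whose samples do not overlap between the groups; for the mean and the trend the largest changes are named, and where no feature passes those with the smallest p. Alternatives were median centring of each array, quantile normalization, the arrays of each orientation alone, all 16 arrays with a dye term, the median of spots, a filter on disagreement between dye swaps, a robust prior, a minimum change, the set letter as a block, only the doses compared, and leaving out each sample in turn, which assumes that the lone sample left at a dose varies like the other groups. In the fits to single arrays with a dye term, the dye-swap arrays of a sample formed a block with a correlation estimated over all features. Data were simulated for 1.0 against 0.0 mM with 200 of 2675 features changed (20 draws). A change of 0.1 was called in 30.4% of features, 0.2 in 84.8%, 0.3 in 97.2%, and 0.242% of unchanged features were called. The simulated noise was normal and independent between features and samples, with the residual spread of each feature. It held no dye effect, array run or flawed array, so these rates need not hold for the measured data. Figures were drawn with matplotlib 3.10.9.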

Results

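RNA of a *Halobacterium salinarum* NRC-1 strain, labelled as a knockout of *ura3* and vng1179, was compared at 4 copper doses. At each of 0.0, 0.7, 0.85 and 1.0 mM copper there were 2 samples, set A and set B, each the mean of 2 dye-swapped arrays against a common control RNA. The labels present the series as a study of the copper response of this strain. Of 2675 features tested, 133 carry a gene name. Across features, set A and set B correlated at 0.83, 0.88, 0.77 and 0.93 from the lowest to the highest dose; features are not independent replicates. Genes of copper efflux carry no name in the annotation used here, so their response was not read.

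*pyrF* (*ura3*), the gene for orotidine phosphate decarboxylase of uracil synthesis, was measured first because the labels name it as knocked out. Its ratio to the control RNA without copper was -0.11 ± 0.027 log-ratio units (SE, n = 2), with an adjusted p of 0.0095 (limma). It lay below 0 in 6 of 8 samples and at 25 of 28 spot values. Its spots 10367 and 10368 had no value in set A of 0.7 mM or in set A of 0.85 mM. The arrays with the sample in channel 1 alone gave 0.30 and those with it in channel 2 alone -0.52; single orientations keep the dye effect that their mean cancels. A difference as small as that of the mean (1.29-fold if the base is 10, 1.08-fold if it is 2) is a weak check of the direction and does not show the loss of the transcript, so the deletion is not borne out by these values; the labels do not say whether the control carries the gene. No probe carries the name of vng1179 in the annotation used here.

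At 1.0 mM copper against 0.0 mM, *psmB*, a subunit of the proteasome that breaks down proteins, rose by 0.34 ± 0.035 log-ratio units (SE, n = 2 per dose). Of the genes of arginine fermentation, *arcC* (carbamate kinase) rose by 0.25 ± 0.035 and *arcA* (arginine deiminase) by 0.23 ± 0.038. *serB*, for the last step of serine synthesis, rose by 0.24 ± 0.031 and *argH*, for the last step of arginine synthesis, by 0.20 ± 0.033. *gdhA1*, a glutamate dehydrogenase, fell by 0.28 ± 0.031. In pyrimidine synthesis, *pyrI* (the regulatory subunit of aspartate carbamoyltransferase) fell by 0.27 ± 0.038 and *carB* (carbamoyl phosphate synthetase) fell by 0.22 ± 0.033. The adjusted p (limma) of these genes ran from 1.4e-05 for *psmB* to 0.00098 for *arcA*. Smaller rises were found for *hutG* (histidine breakdown, 0.13), *htr1* (the transducer of sensory rhodopsin I, 0.12) and *thiC* (thiamine synthesis, 0.11). The cobalamin genes *cbiT* and *cobN* had changes of -0.17 and -0.15, *glyA* (serine hydroxymethyltransferase) -0.13 and *sucD* (succinyl-CoA synthetase) -0.11, with adjusted p from 0.013 for *glyA* to 0.030 for *sucD* (limma). Among features without a name, probes 4155 and 3587 rose by 0.66 and 0.59, while probes 4845 and 4795 had changes of -0.46 and -0.43; probe 4795 is among the features that were off on the array with set A of 0.85 mM in channel 1. If the deposited logarithm has base 10, the rise of *psmB* is 2.17-fold, and if it has base 2, 1.26-fold.

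In all, 291 of 2675 features changed at 1.0 mM, 185 higher and 106 lower, 15 of them named (727 had an unadjusted p under 0.05). The doses compared fall in different runs of array numbers, so dose and run are not separated in this comparison alone. All 15 named genes moved the same way in both dye orientations, as did 263 of the 291 features, but these were called on the mean of both. On the arrays with the sample in channel 1 alone *psmB* was the only 1 of the 15 past the threshold, and on those with it in channel 2 alone 10 were. Each channel 1 fit takes in, through the shared spread, the array with set A of 0.85 mM that stands outside both runs. Centring each array on its median gave 134 higher and 174 lower features and quantile normalization 140 and 196. No named gene turned direction, but *hutG* passed the threshold under neither scaling, *thiC* not after centring, and *glyA* and *sucD* not after quantile normalization. Without set A or set B of 0.0 mM, 94 and 116 features passed; without set A or B of 1.0 mM, 85 and 94; and without set A or B of 0.85 mM, which enter only through the shared spread, 481 each. *psmB*, *arcC*, *serB*, *arcA*, *argH*, *gdhA1*, *pyrI* and *carB*, 8 of the 15 named genes, passed with any of the 8 samples left out.

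**Figure D1:**
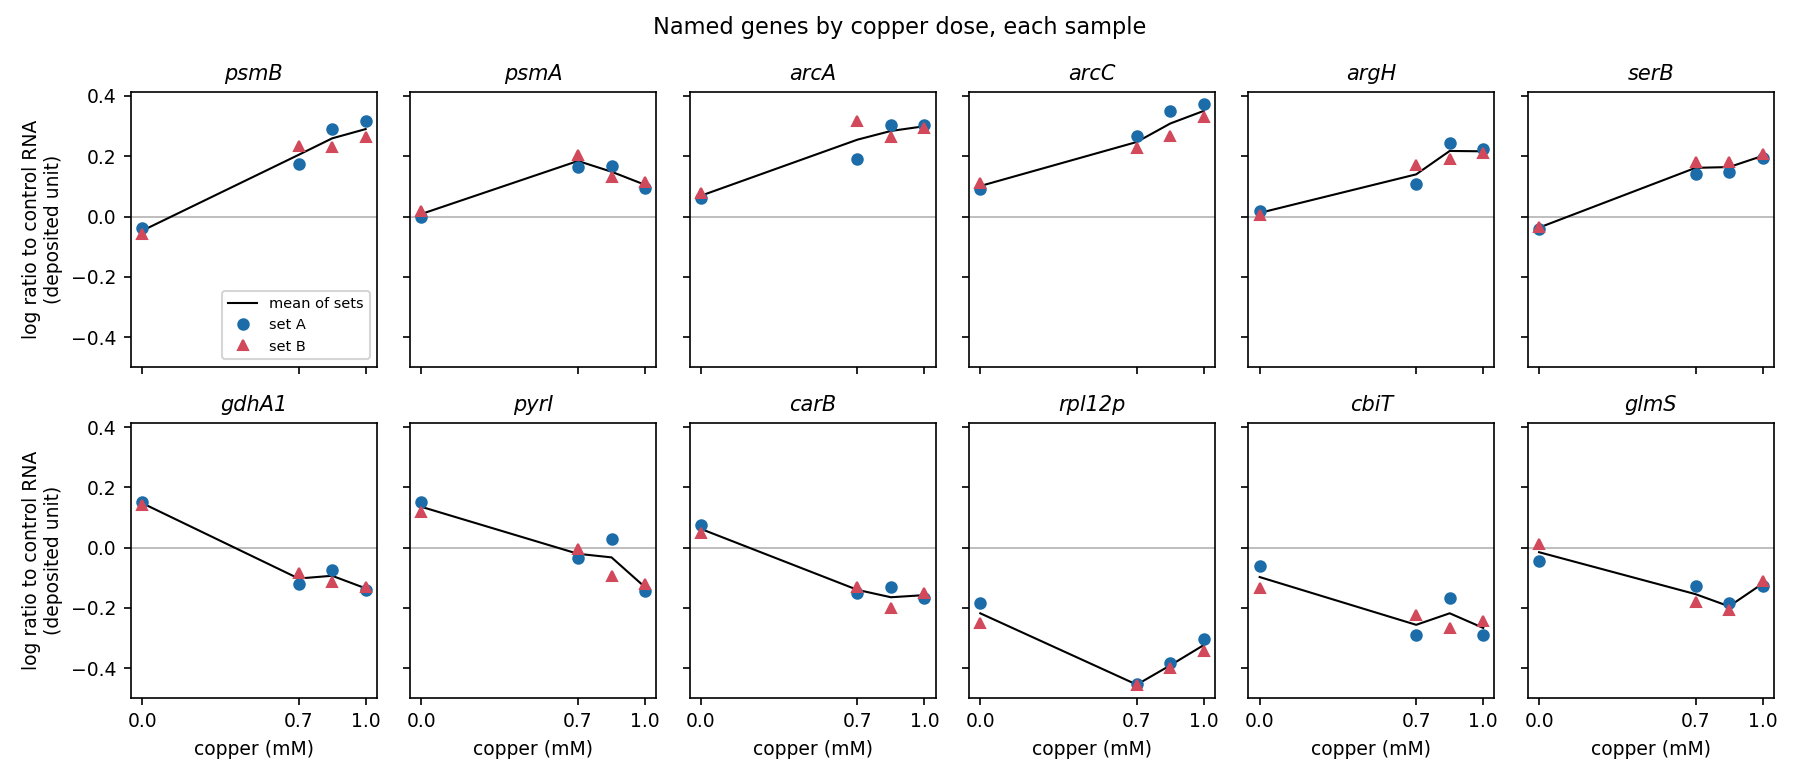
Log ratio to the control RNA (deposited unit, y axis) of 12 named genes against copper dose in mM (x axis); circles are set A, triangles set B and lines the mean of both sets. *psmB* lies at -0.05 without copper and at 0.29 at 1.0 mM, and *gdhA1* at 0.15 and -0.13.

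At 0.85 mM copper against 0.0 mM, *psmB* rose by 0.31 ± 0.035 and *psmA*, the other core proteasome subunit, by 0.14 ± 0.031 (SE, n = 2 per dose). *arcA*, *arcC* and *argH* each rose by 0.21 (SE 0.038, 0.035 and 0.033) and *serB* by 0.20 ± 0.031. *gdhA1* fell by 0.24 ± 0.031, *carB* fell by 0.23 ± 0.033 and *pyrI* fell by 0.17 ± 0.038. *glmS*, for the amino sugar glucosamine 6-phosphate, fell by 0.18 ± 0.033 and *rpl12p*, a ribosomal protein of the large subunit, fell by 0.17 ± 0.033. Their adjusted p (limma) ran from 5.0e-05 for *psmB* to 0.011 for *pyrI*. Smaller changes past the threshold were those of *htr1* (0.12), *glpK* (glycerol kinase, -0.14), *folP* (folate synthesis, -0.12) and *lysS* (lysyl-tRNA synthetase, -0.11). Probes 4155 and 3587 rose by 0.62 and 0.55, and probes 3613 and 1223 had changes of -0.35 and -0.29. In total 210 features changed, 136 higher and 74 lower, 15 of them named (619 had an unadjusted p under 0.05). With the sample in channel 1 alone *psmB* was the only 1 of the 15 past the threshold, and in channel 2 alone 11 were. The array with set A of 0.85 mM in channel 1 enters this comparison, and the doses again fall in different runs of array numbers. Median centring gave 123 higher and 106 lower and quantile normalization 111 and 120, with *arcC*, *htr1*, *rpl12p* and *lysS* no longer past the threshold under the latter. Without set A or B of 0.0 mM 79 and 109 features passed, and without set B of 0.85 mM 409; *psmB*, *arcA*, *arcC*, *argH*, *serB*, *gdhA1* and *carB*, 7 of 15 named genes, passed with any sample left out.

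At 0.7 mM copper, whose arrays share a run of array numbers with those of 0.0 mM, *psmB* rose by 0.25 ± 0.035 and *psmA* by 0.18 ± 0.031 (SE, n = 2 per dose). *serB* rose by 0.20 ± 0.031, *arcA* by 0.19 ± 0.038, *arcC* by 0.15 ± 0.035 and *argH* by 0.13 ± 0.033. *panB*, for the first step towards pantothenate, rose by 0.16 ± 0.031, and *htr1* by 0.12 ± 0.031. *gdhA1* fell by 0.25 ± 0.031, *rpl12p* fell by 0.24 ± 0.033, *carB* fell by 0.20 ± 0.033 and *pyrI* fell by 0.16 ± 0.038. *cbiT*, *glmS*, *icd* (isocitrate dehydrogenase) and *cmk* (cytidylate kinase) had changes of -0.16, -0.14, -0.12 and -0.12. The adjusted p (limma) of these genes ran from 0.00014 for *gdhA1* to 0.040 for *cmk*. Probes 4155 and 3587 rose by 0.60 and 0.57, and probes 1085 and 3613 had changes of -0.32 and -0.31. In total 199 features changed, 92 higher and 107 lower, 16 of them named (484 had an unadjusted p under 0.05). All 16 moved the same way in both dye orientations, as did 183 of the 199 features, but these were called on the mean of both. Of all features, 57.5% had the same sign in both. Of the 16, 1 (*psmB*) was past the threshold on the channel 1 arrays alone and 8 on the channel 2 arrays alone. After quantile normalization *arcC*, *argH*, *rpl12p*, *cbiT*, *icd* and *cmk* were not past the threshold. Without set A or B of 0.0 mM 56 and 89 features passed, and without set A or B of 0.7 mM 98 and 74; *psmB*, *serB*, *gdhA1*, *rpl12p* and *carB*, 5 of 16 named genes, passed with any sample left out.

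Across the doses, *arcA*, *arcC*, *argH*, *htr1*, *psmB* and *serB* rose at all 3 and *carB*, *gdhA1* and *pyrI* fell at all 3. Each of these 9 genes lay beyond both samples without copper in 6 of 6 copper samples, which follows from the rule that named them. Of all features, 72 were higher at all 3 doses, 38 lower at all 3, and 398 changed at 1 dose or more, 24 of them named. Over the mean of the 3 doses *psmB* rose by 0.30 ± 0.029 and *gdhA1* fell by 0.26 ± 0.026 (adjusted p 5.4e-06 and 6.6e-06, limma), and 276 features changed, 159 higher and 117 lower (660 had an unadjusted p under 0.05). The 2 largest changes in each direction were at features without a name, probes 4155 and 3587 with 0.63 and 0.57 and probes 3613 and 1849 with -0.35 and -0.32. Over the linear trend, *psmB* rose by 0.35 ± 0.034 per mM and *gdhA1* fell by 0.29 ± 0.034 per mM (adjusted p 1.6e-06 and 1.3e-05, limma). No dose lies between 0.0 and 0.7 mM, so a single step with copper can pass the trend and the slopes do not show a graded response. Between 1.0 and 0.7 mM *psmB* differed by 0.086 and *gdhA1* by -0.033, neither past the threshold (adjusted p 0.21 and 0.60, limma). The trend was past the threshold at 237 features, 146 rising and 91 falling (580 had an unadjusted p under 0.05), with the largest slopes at probes 4155 (0.69), 3587 (0.63), 3613 (-0.39) and 4845 (-0.39). Median centring gave 149 higher and 175 lower for the mean and 114 and 132 for the trend; quantile normalization gave 150 and 193, and 130 and 177. Without set A or B of 0.0 mM the mean had 105 and 143 features and the trend 84 and 87, and without set B of 0.85 mM the mean had 450.

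**Figure D2:**
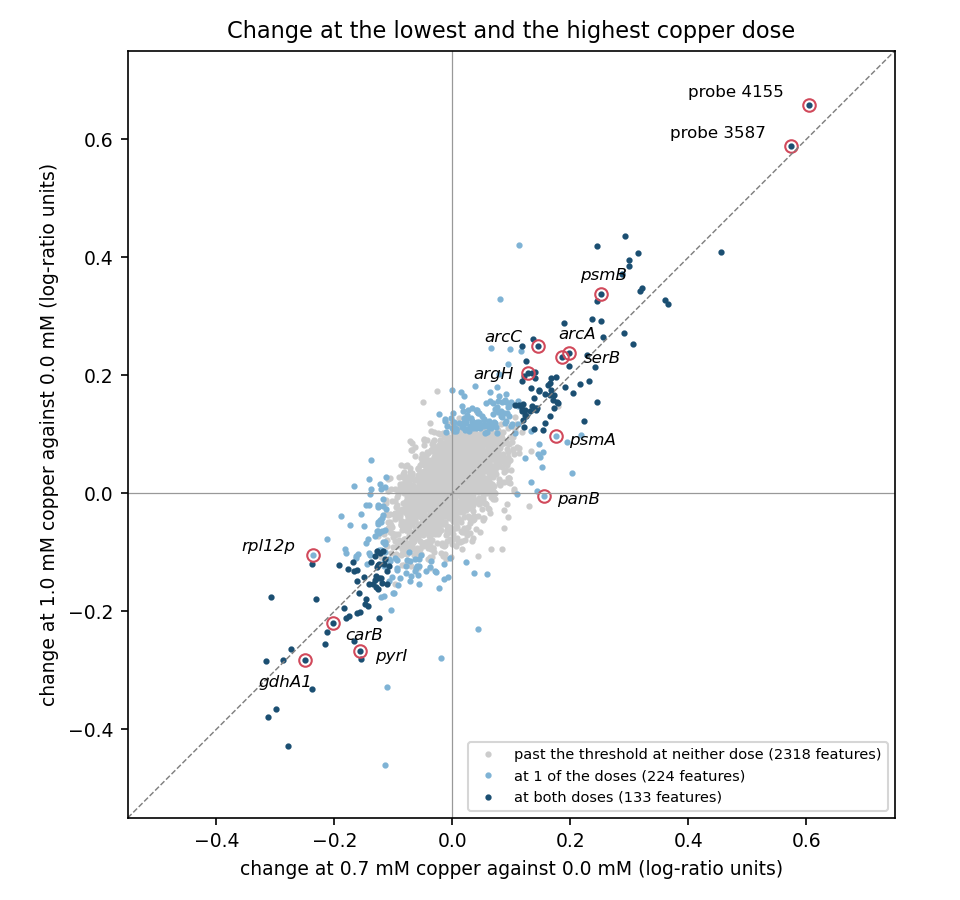
Change at 1.0 mM (y axis) against change at 0.7 mM copper (x axis), both against 0.0 mM in log-ratio units, for each of 2675 features; dark points passed the threshold at both doses (133), light blue points at 1 of them (224) and grey points at neither (2318), and the dashed line marks equal change. *psmB* lies at 0.25 and 0.34, and *panB* at 0.16 and -0.0045.

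The comparisons with 0.0 mM share the same 2 control samples, which gives their changes a correlation with no effect at all. The changes at 0.7 and 1.0 mM correlated at 0.74 across features, against 0.50 in 100 simulations without effects, with a covariance of 0.0039 against 0.00077. Features higher at both numbered 77 and lower at both 56, none moved in opposite directions, and lists of these sizes drawn independently would share 6.36 and 4.24. For 0.7 and 0.85 mM the correlation was 0.80 and for 0.85 and 1.0 mM it was 0.75. The difference of the covariances, 0.0031, leaves out what the spread between the 2 control samples adds. A deviation common to both control samples would stay in it, and the simulations cannot show that. With 2 controls no split leaves 2 in each part, so part of the excess of shared features may come from the shared controls.

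Between copper doses, *panB* was lower at 1.0 than at 0.7 mM, with a change of -0.16 ± 0.031 (adjusted p 0.024, limma); its ratio to the control RNA was 0.20 ± 0.0038 at 0.7 mM, 0.15 ± 0.018 at 0.85 mM and 0.045 ± 0.016 at 1.0 mM (SD, n = 2). It was the only named gene among 29 features that differed between these doses, 22 higher and 7 lower at 1.0 mM (521 had an unadjusted p under 0.05), in a comparison added after the data were seen and across runs of array numbers. *rpl12p*, which fell at 0.7 mM, differed between them by 0.13 ± 0.033 and *icd* by 0.13 ± 0.032, neither past the threshold (adjusted p 0.070 and 0.071, limma). The doses 1.0 and 0.85 mM share a run, except for the array with set A of 0.85 mM in channel 1, which stands outside it. Between these doses limma called 0 features, with 401 at an unadjusted p under 0.05. Those with the smallest p, all without a name, were probes 97 (0.16) and 285 (0.17), higher, and probes 4809 (-0.17) and 4845 (-0.20), lower, each with an adjusted p of 0.082. Without set A of 0.85 mM 4 features passed, without set B of 0.85 mM 169 and without set A of 1.0 mM 1; all 16 arrays with a dye term gave 20.

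By gene list, pyrimidine synthesis was lower at each copper dose than other genes with camera at a preset correlation, but at no dose with an estimated correlation. Of its 4 named members *carB* and *pyrI* fell at each dose, and *pyrB* (the catalytic subunit of aspartate carbamoyltransferase) and *carA* (the small subunit of carbamoyl phosphate synthetase) were not past the threshold, with changes of -0.08 and -0.0034 at 1.0 mM; adjusted over the list alone, 3 of 4 fell. *pyrF* was left out of the list beforehand as a labelled knockout. Its value in set A of 0.85 mM lacks spots 10367 and 10368. Its feature adjoins probe 4989, which was off by 1.24 on the channel 1 array of that sample, though *pyrF* itself was not among the features off there. *pyrF* was not past the threshold, with changes above 0 (0.0088, 0.066 and 0.087 from the lowest to the highest dose). The adjusted camera p was 0.012, 0.0093 and 0.0049 in the same order, 0.58 at each with an estimated correlation, and 0.043 at each with *pyrF* added to the list after the data were seen. Against no change rather than against other genes, fry gave 0.055, 0.055 and 0.0496. On the channel 1 arrays alone the camera p was 0.10, 0.022 and 0.055, and on the channel 2 arrays alone 0.019, 0.11 and 0.0095. Without set B of 0.85 mM the pyrimidine list at 0.85 mM had an adjusted p of 0.053.

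Chaperones and proteases were higher than other genes at 0.7 and 0.85 mM with camera at a preset correlation (adjusted p 0.038 at both), but not with an estimated correlation (0.58). The members that rose were *psmA* and *psmB*, 2 of 5; the chaperones *dnaK* and *dnaJ* and the proteasome-activating ATPase *pan1* were not past the threshold. The call at 0.85 mM rests in part on *pan1*, whose difference of 0.17 was not past the threshold and which was off on the array with set A of 0.85 mM in channel 1. Without the features off on that array, the adjusted p of the list was 0.066 at 0.85 mM and 0.025 at 0.7 mM. At 1.0 mM, where *psmB* alone of the 5 passed, the adjusted p of the list was 0.087; adjusted over the list alone, 2 of 5 rose there. Against no change, fry gave 0.0496, 0.040 and 0.040 from the lowest to the highest dose. On the channel 1 arrays alone the camera p was 0.055 at 0.7 mM and 0.26 at 0.85 mM, and on the channel 2 arrays alone 0.094 and 0.030. The call of the chaperone list was lost at both doses without set B of 0.0 mM or set A of 0.7 mM, and at 0.85 mM without set A of 0.85 mM (adjusted p up to 0.087). The 2 named members of arginine fermentation, *arcA* and *arcC*, rose at each dose but were too few for a list test.

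The strain without copper was compared with the control RNA to see how it differs from it without added metal. The samples without copper are also those that each copper dose was compared with, so a deviation in them enters both comparisons with opposite sign. The 2 comparisons are therefore not independent. *gdhA1* and *pyrI* were higher here and fell with copper. *arcC* was higher here and rose with copper, and *rpl12p* and *sucD* were lower here and fell at some copper dose. *gdhA1* was higher by 0.15 ± 0.022 log-ratio units (SE, n = 2), with 0.15 in each dye orientation. *hop*, for the light-driven chloride pump halorhodopsin, was higher by 0.10 ± 0.024 (0.09 and 0.10 by orientation), *arcC* by 0.10 ± 0.025 (0.15 and 0.05) and *pyrI* by 0.14 ± 0.027 (0.0058 and 0.27). The ribosomal proteins *rpl12p* and *rpmC* had ratios of -0.22 ± 0.023 and -0.20 ± 0.065, the chaperone *dnaK* -0.13 ± 0.024 and *mdh* (malate dehydrogenase) -0.13 ± 0.024, each below 0 in both orientations. *secY* (protein export, -0.21 ± 0.024), *eno* (enolase, -0.18 ± 0.022), *sucD* (-0.12) and *ppsA* (phosphoenolpyruvate synthase, -0.11) were lower, and *dpsA* (a ferritin-like protein that guards DNA, 0.13), *trpC* (tryptophan synthesis, 0.09), *purF* (purine synthesis, 0.08) and *pyrB* (0.07) higher; these 8 had opposite signs in the 2 orientations. The adjusted p (limma) of the genes named ran from 8.6e-06 for *rpl12p* to 0.046 for *pyrB*. Probes 1605 and 4845 were higher by 0.81 and 0.58, and probes 4433 and 1007 had ratios of -0.59 and -0.40.

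Against the control RNA 462 features differed, 223 higher and 239 lower, 35 of them named (835 had an unadjusted p under 0.05). In single orientations, which keep the dye effect that their mean cancels, 219 of the 462 features and 14 of the 35 named genes had the same sign in both. Of all features 15.8% did, though the 462 were called on the mean of both orientations. Quantile normalization gave 644 higher and 397 lower and median centring 176 and 321, after which *trpC* and *pyrB* were not past the threshold. Without set A or B of 0.0 mM 162 and 135 features passed; *gdhA1*, *rpl12p*, *secY* and *eno* passed with any sample left out. The citric acid cycle list (3 of 6 members lower, *mdh*, *sucD* and *sdhC* of succinate dehydrogenase) and the cobalamin list (2 of 4, *cbiT* and *cbiG*) were lower than other genes, with adjusted camera p of 0.015 and 0.045 and 0.58 for both with an estimated correlation. On the arrays with the sample in channel 2 alone both lists pointed up, with adjusted p of 0.023 and 0.14. The first call was lost without set B of 0.0 mM (0.056), and the second without set A or B of 0.0 mM or set A of 0.7 mM (up to 0.081) and without the features off on the array named above (0.055).

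**Figure D3:**
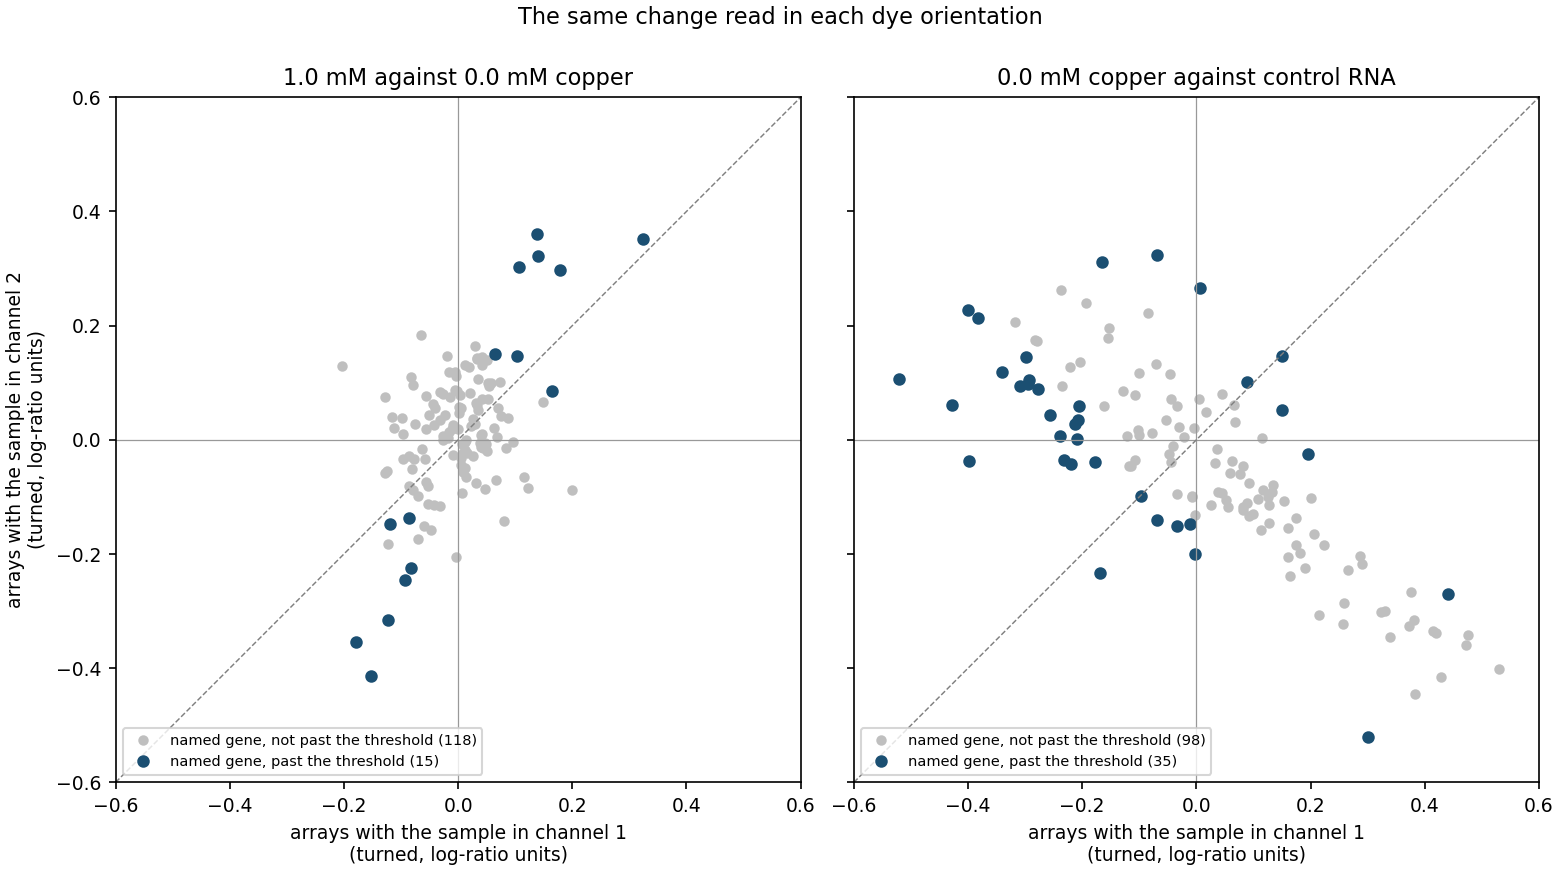
Change of 133 named genes read from the arrays with the sample in channel 1 (x axis) and in channel 2 (y axis), both turned to the same direction, in log-ratio units, for 1.0 against 0.0 mM copper (left) and 0.0 mM against the control RNA (right); dark points passed the threshold and the dashed line marks equal change. The 15 genes past the threshold on the left have the same sign on both axes, and 14 of 35 do on the right.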

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

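The comparison of each array with the other 3 of its dose was fixed beforehand; the tests of what lies behind the exact zeros and the deviating features were chosen after they were seen. Of 24 such comparisons (6 measures at 4 doses) 2 found an array apart, and chance gives about 1 in 20. Both concern the number of spots with an exact 0. On the array with set A of 0.7 mM in channel 2 there were 99 such spots, and 0 on each other array of that dose. With the others tied at 0, any count above 0 would have set that array apart. At 0.0 mM each array had 0 such spots, so that comparison could find none. The rate of 1 in 20 does not hold for such tied counts.

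The array with set A of 0.85 mM in channel 1 had 823 spots at exactly 0, against 128 on the next array of its dose. Ratios that are truly 1 are argued against, because the same spots had a median size of 0.466 on the other channel 1 arrays (95% bootstrap interval 0.458 to 0.474), over the 0.226 of all spots there, and 0.481 where the adjacent duplicate was 0 as well (552 of the 823). Of its features, 39 were over 0.3 off the other channel 1 arrays, which had 3 to 6 such features each, and 56.4% of the 39 had an adjacent feature off as well, against 2.72% on average in 1000 permutations, so a local flaw of the array may be the source. A difference of the culture is argued against, because the dye-swap partner of the same sample was off by -0.0635 of the deviation, in the other direction. The named genes among the 39 are *rpmC* (0.10 in set A and -0.36 in set B), *speB* (0.22 and -0.21) and *pan1* (0.25 and 0.03), and for these the set A value at 0.85 mM should not be read.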

How the results depend on the processing

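Of 2383 values of named genes and features (94 pairs of a gene and a comparison under the alternatives that apply to it), 1825 kept their direction and side of the threshold, 522 kept their direction but were no longer past it, 23 kept it and became so, and 13 turned direction. Some alternatives leave the estimated change as it is, so for them the kept direction was fixed in advance. These are the robust prior, the minimum change, the set as a block, only the doses compared and all 16 arrays with a dye term. Leaving out other features, or a sample of a dose not compared, likewise cannot turn a difference between doses. The 13 turned values belong to *pyrF* and to genes compared with the control RNA. *pyrF* at 0.7 mM was -0.15 on channel 1 arrays, -0.0021 with the median of spots and ranged from -0.018 to 0.035 with samples left out, its change at 0.85 mM was -0.065 with set A of 0.85 mM from its other array alone, and its ratio to the control RNA was 0.30 on channel 1 arrays. Against the control RNA, channel 1 arrays gave -0.068 for *dpsA* and -0.17 for *pyrB*, and channel 2 arrays -0.27 for *trpC*, -0.025 for *purF*, 0.11 for *secY*, 0.061 for *eno*, 0.0065 for *sucD* and 0.12 for *ppsA*.

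Counts of features past the threshold follow in the order 0.7, 0.85 and 1.0 mM, mean, trend, 1.0 against 0.85 mM, and control RNA, where they moved by over 1.5 times. Channel 1 arrays alone gave 9, 37, 17, 17, 7, 1 and 2096. Channel 2 arrays alone, equal in number, gave 123, 213, 215, 268, 221, 0 and 1962, so the number of arrays does not account for the lower dose counts of channel 1. The channel 1 fits include the array with set A of 0.85 mM that stands outside both runs, which enters every dose comparison through the shared spread. Its part in the lower counts was not tested. Against the control RNA a single orientation keeps the whole dye effect. Taking set A of 0.85 mM from its other array alone gave 0, 0, 1, 3, 8 and, against the control RNA, 10, because that sample then keeps its dye effect and widens the shared spread. A minimum change of 1 on the log2 scale gave 12, 17, 23, 15, 24 and, against the control RNA, 11 if the deposited base is 10, and 0 in each of these 6 if it is 2, a reading added after the data were seen. Only the doses compared gave 132 at 0.85 mM and 518 at 1.0 mM. Quantile normalization gave 1041 against the control RNA. Between 1.0 and 0.85 mM, where 0 features passed, median centring gave 2, all 16 arrays with a dye term 20, the filter on dye-swap disagreement 10 and the median of spots 1. For the list tests, with 7 calls, channel 1 arrays gave 3, an estimated correlation 0, and fry 11, of which 4 are among the 7. The cause was not tested except where given.

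With samples left out the counts ran from 56 to 271 at 0.7 mM, 79 to 409 at 0.85 mM, 85 to 481 at 1.0 mM, 105 to 450 for the mean, 84 to 293 for the trend, 0 to 169 for 1.0 against 0.85 mM, 135 to 653 against the control RNA and 3 to 7 list calls; fewer samples at a dose raise its standard error. Samples of the same set letter deviated together at correlations from -0.15 to 0.10, which does not settle what the letter stands for. The set as a replicate block gave 189, 202, 292, 279 and 216 for the doses, mean and trend and 1 between 1.0 and 0.85 mM, and changed no list call. On the 4 samples of 0.7 and 0.0 mM, crossed pairing gave 346 calls and same-letter pairing 226.

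Further alternatives were chosen after seeing the data. Fits to 15 arrays with a dye term, without the array with set A of 0.85 mM in channel 1, gave 482 at 1.0 mM, 463 for the mean and 16 between 1.0 and 0.85 mM; with all 16 arrays and the same term they gave 383, 375 and 20, so much of the rise over the sample means comes with the array fit. Leaving out the features off on that array gave 2 between 1.0 and 0.85 mM and 5 of the 7 list calls, and adding *pyrF* to the pyrimidine list kept all 7. The first 2 spots of each feature alone gave 132 at 0.7 mM, 123 at 1.0 mM, 100 for the trend, 29 between 1.0 and 0.85 mM and 290 against the control RNA; the other 2 spots gave 70, 127, 86, 147, 129 and, against the control RNA, 201. Exact zeros kept as values moved no count by over 1.5 times. Signal over background was not analysed here.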

Other observations

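The tests of array runs, of dye bias and of probe 4433 in this part were chosen after the results were seen.

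Among glutamate and glutamine genes *gdhA1* fell at each dose, while *gdhA2*, *gdhB* and *glnA* were not past the threshold. In cobalamin synthesis *cbiT* fell at 0.7 and 1.0 mM and *cobN* at 1.0 mM, 2 of 4 members, with an adjusted camera p of 0.059 for the list at 1.0 mM, the lowest of the lists not called in the dose comparisons. In the citric acid cycle *icd* fell at 0.7 mM and *sucD* at 1.0 mM, of 6 members. Of 11 flagella and chemotaxis genes *htr1* rose at each dose; of 12 aminoacyl-tRNA synthetases *lysS* fell at 0.85 mM; *hutG*, of 3 histidine breakdown genes, and *thiC*, of 3 thiamine genes, rose at 1.0 mM. No member of the lists of DNA repair (4), purine synthesis (7), histidine synthesis (6), aromatic amino acid synthesis (4), protein export (3), DNA topology and replication origin (4) or rhodopsins and carotenoids (4) passed the threshold at any copper dose.

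The 291 features changed at 1.0 mM were weighed against the run of array numbers and against dye bias. Features chosen with set A of 0.0 mM and measured at 0.7 mM, in the run of 0.0 mM, against set B had the same sign as at 1.0 mM in 96.6% of 116 cases, with a median change of 0.14 at 0.7 mM and 0.20 at 1.0 mM. With the sets exchanged it was 94.7% of 94 features, which argues against the run as the whole cause for features so chosen, while a share in the size of the change stays open. For the others of the 291 the run was not tested. Over all features, 69.5% had the same sign at 0.7 and 1.0 mM, against 66.7% in simulations without effects. Of 215 features called on the channel 2 arrays alone, 70.7% had the same sign on the channel 1 arrays, where their median change was 0.06 against 0.26; at 0.7 and 0.85 mM it was 75.6% of 123 and 63.4% of 213. Of all features, 57.5%, 45.1% and 63.6% had the same sign in both orientations at 0.7, 0.85 and 1.0 mM. These are values of single orientations, and a dye effect equal in both arrays of a sample cancels in the means that were called. Of the dye effect, a part that differs between the arrays of a sample stays open, untested. A share of the run and a deviation common to both samples of 0.0 mM also stay open beside the response to copper.

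Probe 4433, an unnamed feature chosen after its values were seen, lay within the lowest 1% of features in 8 of 8 samples and was the lowest in 6, with a mean ratio to the control RNA of -0.60 (SD 0.070). On single arrays it was the lowest on 7 of 16. Whether it is a probe of vng1179, labelled as knocked out, cannot be decided here, since it has no name in the annotation used here, was picked for being low, and the direction of the ratio is not stated. The other labelled knockout, *pyrF*, had a ratio of only -0.11 without copper. At the other end, probe 1605 had a mean ratio of 0.75 (SD 0.12) and was the highest in 6 of 8 samples.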
